A study of Mus musculus with 18 samples.

How the data were processed

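Expression was measured by Smart-seq2 in 18 mouse embryo libraries, 12 of the siRNA experiment and 6 of the treatment experiment, sequenced as paired reads of 150 nt per the labels. Per the submitters' processing notes, reads were trimmed with cutadapt 1.16 and aligned with STAR to mm10. The program that made the expression values, its annotation and the STAR version are not given in the sources used here. The authors deposited FPKM values (fragments mapped to a gene, scaled by its exon length and by all mapped fragments), 1 file per library with 55335 genes each, so each library had been scaled by its own depth and each gene by its length. These files hold no read counts and keep no strand, so reads of a gene and of an overlapping or antisense gene stay together. Genes of multi-copy families (Zscan4, Tdpoz, Usp17l, Omt2, Oas1, Fbxw, Obox) share reads. Groups came from the sample titles. For replicates 2 and 3 of siEchs1 L2C the titles and the file headers disagreed on the number, and the titles were used.

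The planned analysis had a branch for counts and one for normalized values, and the second was used. Genes whose symbol occurs more than once (107 symbols, 216 entries) and 27 symbols turned into dates were left out, which left 55098 genes. Values were tested as log2(FPKM + 1), computed from the deposited FPKM, among genes with at least 1 FPKM in at least 3 siRNA libraries (17652 genes) or at least 2 treatment libraries (13789 genes). Fold changes are on this scale, which understates changes of genes with low values. The test was limma-trend with robust variance (limma 3.58.1, R 4.3.3), with all 12 siRNA libraries in 1 fit and all 6 treatment libraries in another, group means and no other covariate. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no fold minimum, and calls of at least 2-fold were counted as well. Adjusted p-values of single genes are from this test, and all tests were two-sided. The comparisons were siEchs1 against siCon at E2C and at L2C, the difference between these effects, L2C against E2C in siCon, and crotonate against DMSO, acetate against DMSO and crotonate against acetate.

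A total of 29 gene lists fixed in advance were tested with camera at a preset correlation of 0.01 and adjusted over the lists of a comparison. They covered 2-cell transient genes, embryonic activation, ribosome biogenesis, ribosomal proteins, oocyte transcripts, mRNA decay, crotonyl-CoA and histone crotonylation, fatty acid oxidation, branched-chain amino acid catabolism, nuclear oxidative phosphorylation, the mitochondrial genome, the TCA cycle, glycolysis, cholesterol and lipid synthesis, histone variants, chromatin modifiers, the transcription machinery, splicing, the proteasome, G2/M, DNA replication, the p53, ATF4 and interferon responses, and lineage and pluripotency. Markers of cumulus and granulosa cells, sperm and testis, blood and oviduct epithelium stood for other cells that a tube of embryos could hold. A list needed 5 measured members. Camera was repeated with the correlation between genes estimated from the data, and fry was run beside it. With the estimated correlation 0 of the 29 lists passed in any comparison, and of the stage sets described below the falling set did in siEchs1 E2C and both sets did for the difference of siRNA effects. The median or mean of a list differed in sign from its camera direction in 34 cases over all comparisons, of which 0 were called (lowest adjusted p = 0.196). Sets of stage-rising and stage-falling genes were those with an adjusted p under 0.05 and a log2 change of at least 2 in the mean of both siRNA arms, a contrast orthogonal to the siRNA effects.

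The named genes followed a fixed rule. They were Echs1, the 6 largest changes per direction among called genes whose libraries did not overlap between groups and whose mean was at least 5 FPKM (predicted genes and pseudogenes left out), up to 4 called members with the smallest adjusted p of each list that passed camera or had at least 3 called members, and 21 genes chosen in advance for their role in the 2-cell stage, the oocyte or crotonylation. Groups, comparisons, lists, this rule and a set of other settings were chosen before the data were examined. Those settings were quantile normalization, no filter on low values, no trend, a pseudocount of 0.1, the replicate number as a block, leaving out each library in turn, fits of the compared libraries alone, a smaller stage change of 1 for the stage sets, and a mean of at least 5 FPKM for correlations across experiments. Protein-coding genes alone, values rescaled without mitochondrial transcripts and 2 ribosomal RNA genes, the block with the header numbers, the named-gene rule on protein-coding genes alone, lists under each scaling and lists without each library were added after the data had been seen. The 2 ribosomal RNA genes were CT010467.1 and AY036118, the latter listed at 0 in every siRNA library and at 7576 to 11998 FPKM in the treatment libraries, and the 2 experiments were fitted apart. Relative to the reported values, quantile normalization moved the median log2 fold change of all genes from 0.51 to -0.01 for the stage change, from -0.21 to 0.00 for the difference of siRNA effects and from -0.15 to -0.01 for crotonate against DMSO. Rescaling moved it from 0.15 to 0.31 for siEchs1 at E2C, from -0.08 to -0.19 for acetate against DMSO and from -0.09 to 0.05 for crotonate against acetate, and to 0.77 and -0.40 for the stage change and the difference of siRNA effects. Among lists called by camera the median kept its direction under both scalings, except that of sperm and testis markers in the stage change. The mitochondrial genome list had no value after rescaling, which removes its genes.

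Gene types, positions and exon lengths came from the GENCODE M21 annotation of mm10, in which 55154 of 55335 gene IDs were found (99.67%). Depth was estimated per library by taking the smallest steps of low values as single fragments, too roughly to derive counting intervals. Zeros may be failed estimates, so for genes listed at 0 in a whole group each library's value is given and no fold. In data simulated from real means and spreads, only 100 genes per size were changed, by 1 or 2 (log2). The siRNA comparisons called far more, so these rates do not give their power. Of genes changed by 2, 44% were recovered for siEchs1 at L2C, 37% at E2C and 54% for the stage change. The share was 69% for crotonate against DMSO, 63% for acetate against DMSO and 66% for crotonate against acetate. Of genes changed by 1, 1% to 5% were recovered. False calls made up 4.17%, 7.32%, 9.68%, 12.2%, 12.8% and 14.6% of the calls in that order, above the nominal 5% in all but the first. A correlation expected from shared DMSO libraries was simulated in 100 draws. Tables were processed with python 3.11.15 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.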

Results

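RNA of early mouse embryos was sequenced in 18 libraries in a series on histone crotonylation, the addition of crotonyl groups to histone lysines. Each library was made with Smart-seq2, a full-length protocol for poly(A) RNA, from a tube of 5 to 10 embryos. In the siRNA experiment, a control siRNA (siCon) and an siRNA against Echs1 (siEchs1) were compared at stages labelled E2C and L2C, with 3 libraries in each of 4 groups. In the treatment experiment, zygotes received sodium crotonate, sodium acetate or DMSO and were collected as early 2-cell embryos (E2C), with 2 libraries in each of 3 groups. The labels gave no doses and did not spell out L2C. Values were FPKM, and their total per library lay between 708113 and 1123990. In the siRNA experiment 13378 to 16703 genes reached 1 FPKM in a library, and in the treatment experiment 12037 to 12856 did. Depth was estimated from the smallest steps of low values at 10.22 to 23.15 M fragments per library, with a median of 18.18 M. That estimate was rough, because 41.5% to 53.1% of low values came out within 0.15 of a whole fragment, against 30% by chance.

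Mitochondrially encoded transcripts took 13.1%, 17.0% and 15.7% of the FPKM total in siCon E2C and 2.82%, 1.69% and 10.3% in replicates 1 to 3 of siEchs1 E2C. At L2C they took 7.58% to 11.2% in siCon and 0.831% to 2.27% in siEchs1. Replicates of a group correlated across genes at 1 FPKM or more in either library, with a Spearman rho of 0.902 to 0.915 in siCon E2C, 0.861 to 0.895 in siCon L2C, 0.908 to 0.937 in siEchs1 L2C, 0.918 in DMSO, 0.848 in acetate and 0.889 in crotonate. In siEchs1 E2C the range was 0.668 to 0.900, and replicate 3 stood apart from the other two. No pair of libraries of an experiment had more than 0.234% of values equal. No label said that replicates came from separate matings or cultures. P-values thus measure only the spread between these samples, which may be technical.

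Echs1, the mitochondrial short-chain enoyl-CoA hydratase that hydrates crotonyl-CoA, was measured first in every library. The gene (ENSMUSG00000025465.13, protein-coding, 8286 nt of annotated exon) lies on chromosome 7 of mm10, from 140105710 to 140116476 on the minus strand. In siCon E2C its level was 30.5, 27.5 and 32.5 FPKM, and in siEchs1 E2C it was 0.71, 5.88 and 3.82 FPKM in replicates 1 to 3. In siCon L2C it was 38.6, 39.2 and 24.4 FPKM, and in siEchs1 L2C it was 0.89, 4.32 and 4.25 FPKM. Echs1 fell with the siRNA at E2C (3.47 ± 2.60 against 30.2 ± 2.54 FPKM, SD, n = 3, log2 fold change -3.02, limma adjusted p = 0.00252) and at L2C (3.15 ± 1.96 against 34.1 ± 8.35 FPKM, -3.19, adjusted p = 0.000435). In the treatment experiment it was 37.4 and 38.4 FPKM in DMSO, 42.6 and 36.2 FPKM in acetate and 32.1 and 27.8 FPKM in crotonate. The 6 libraries of the siEchs1 groups thus lay below the 12 others, which spanned 24.4 to 42.6 FPKM.

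**Figure D1:**
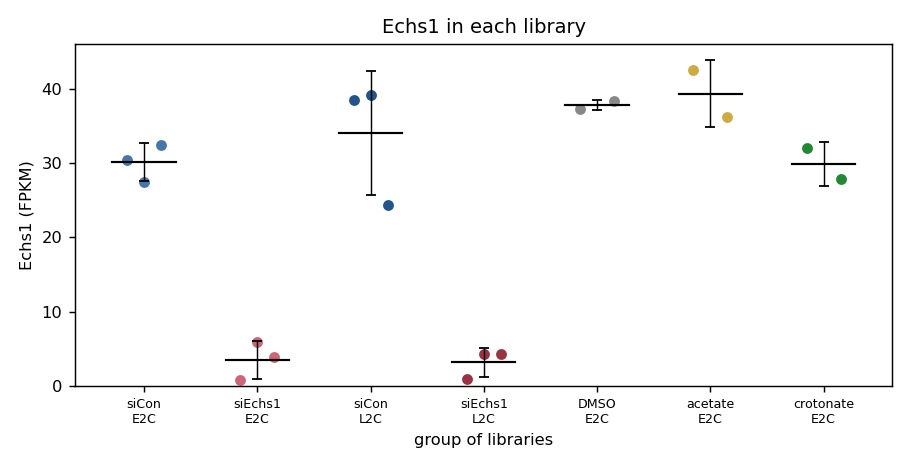
Echs1 in FPKM (vertical axis, linear) in each of the 18 libraries, by group (horizontal axis); dots are libraries, horizontal lines group means and bars the SD. The 6 siEchs1 libraries sit between 0.71 and 5.88 FPKM and the 12 others between 24.4 and 42.6 FPKM.

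The first comparison asked what Echs1 siRNA did to the transcriptome at E2C. Transcripts that mark the 2-cell stage were lower in siEchs1 embryos. Zscan4d, a 2-cell factor tied to telomere maintenance, fell from 124 ± 15.4 to 29.2 ± 5.14 FPKM (SD, n = 3, log2 fold change -2.06, adjusted p = 0.000971). Zscan4c fell from 134 ± 17.2 to 17.6 ± 9.55 FPKM (-2.97, adjusted p = 0.0111). The homeobox gene Obox6 fell from 169 ± 38.8 to 12.4 ± 8.28 FPKM (-3.95, adjusted p = 0.00279). Of 44 measured genes of the 2-cell transient list, 0 rose and 19 fell (0 and 23 adjusted over the list alone), with a median log2 fold change of -1.14. The list was lower by camera (adjusted p = 9.3e-09; adjusted p = 0.664 with an estimated correlation). Without replicate 3 of siEchs1 E2C, 1 of its genes rose and 25 fell. Zfp352 was at 38.3 ± 28.9 against 133 ± 15.7 FPKM (-2.10, adjusted p = 0.0154). Its call ended without replicate 2 (adjusted p = 0.056) or 3 (0.0522) of siCon E2C and with the E2C libraries alone in the fit (0.086). Tcstv3 was at 220 ± 72.2 against 549 ± 93.2 FPKM (-1.36, adjusted p = 0.0298). That call ended without replicate 1 (adjusted p = 0.0593), 2 (0.106) or 3 (0.0828) of siCon E2C or replicate 2 of siEchs1 E2C (0.123). It also ended without the filter on low values, with the E2C libraries alone and under either scaling (0.0604 to 0.0721). The induction factor Duxf3 and the 2-cell gene Usp17le did not pass (adjusted p = 0.247 and 0.81). Zscan4, Obox, Tdpoz and Usp17l genes are near-identical copies, so their single values are uncertain.

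Mitochondrially encoded transcripts fell too. The ATP synthase subunit mt-Atp6 went from 36010 ± 6963 to 5490 ± 3469 FPKM (SD, n = 3, log2 fold change -2.88, adjusted p = 0.000884). Of 13 genes of the mitochondrial genome 0 rose and 10 fell, also adjusted over the list alone, with a median of -2.32 (camera adjusted p = 4.17e-07; adjusted p = 0.725 with an estimated correlation). Cytochrome b, mt-Cytb, was 17447, 32053 and 30624 FPKM in siCon and 3750, 1758 and 6017 FPKM in siEchs1 (-2.92, adjusted p = 0.00157). It did not pass after quantile normalization (-1.36, adjusted p = 0.0598), under which 2 of the 13 genes fell. Nuclear genes of oxidative phosphorylation were higher, with 9 up and 1 down of 75 (7 and 1 adjusted over the list alone, median 0.93, camera adjusted p = 0.013; adjusted p = 0.825 with an estimated correlation). Ndufs7, a core subunit of complex I, was at 118 ± 86.6 against 9.49 ± 1.41 FPKM (2.98, adjusted p = 0.00893), or adjusted p = 0.0742 with the E2C libraries alone. After rescaling without mitochondrial and ribosomal RNA 18 of the 75 rose and 1 fell. Without replicate 3 of siEchs1 E2C 55 of these nuclear genes rose and 1 fell. Their list call ended without replicate 1 (adjusted p = 0.691) or 2 (0.0719) of siEchs1 E2C.

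Oocyte transcripts, which embryos normally degrade, were higher in replicates 1 and 2 of siEchs1 E2C, while Zp3 and Mos in replicate 3 lay near the siCon level. Zp3, an egg coat glycoprotein, stood at 3071, 3622 and 35.9 FPKM in replicates 1 to 3, against 33.7 ± 4.92 FPKM in siCon (SD, n = 3, log2 fold change 4.43, adjusted p = 0.0276). Mos, the kinase that holds the egg in meiotic arrest, stood at 676, 808 and 7.7 FPKM, against 5.55 ± 0.651 FPKM (4.69, adjusted p = 0.0196). The maternal complex gene Khdc3 was at 961, 1221 and 28.8 FPKM, against 11.5 ± 5.28 FPKM (4.82, adjusted p = 0.00801). The oocyte transcription factor Figla was at 100 ± 101 against 0.953 ± 0.558 FPKM (4.58, adjusted p = 0.00869). Of 80 genes of the oocyte list 31 rose and 11 fell (34 and 12 adjusted over the list alone), with a median of 1.19 (camera adjusted p = 0.0198; adjusted p = 0.742 with an estimated correlation). Members that fell included Omt2b, at 8275 ± 3859 against 35350 ± 1256 FPKM (-2.21, adjusted p = 0.000928), but at -0.29 after quantile normalization (adjusted p = 0.576), under which 27 oocyte genes rose and 1 fell. Tcl1b3, a partner of AKT kinases, was at 825 ± 219 against 2537 ± 372 FPKM (-1.64, adjusted p = 0.00213). The deubiquitinase Uchl1 rose from 787 ± 119 to 2623 ± 620 FPKM (1.72, adjusted p = 0.00191). The mRNA decay adaptor Btg4 was at 2712 ± 421 against 5442 ± 835 FPKM and did not pass (-1.0, adjusted p = 0.0805). It passed without replicate 3 of siEchs1 E2C (adjusted p = 0.0358) or of siCon L2C (0.0229). The calls of Mos and Zp3 ended without replicate 1 (adjusted p = 0.0587 and 0.0685), 2 (0.0566 and 0.071) or 3 (0.0573 and 0.083) of siCon E2C. They also ended without replicate 1 (adjusted p = 0.0658 and 0.0925) or 2 (0.087 and 0.119) of siEchs1 E2C. Without replicate 3 of siEchs1 E2C their log2 fold changes were 6.82 and 6.60, and 46 oocyte genes rose and 13 fell. The call of the list ended without replicate 1 (adjusted p = 0.0658) or 2 (0.0719) of siEchs1 E2C. With the E2C libraries alone Mos, Zp3, Khdc3 and Figla did not pass (adjusted p = 0.123, 0.142, 0.0785 and 0.0756), nor did Mos and Zp3 without the filter on low values (0.0618 and 0.0837).

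Proteasome, DNA replication and glycolysis genes were among those raised at E2C. The proteasome subunit Psmd8 rose from 27.8 ± 0.485 to 156 ± 75.4 FPKM (SD, n = 3, log2 fold change 2.33, adjusted p = 0.000978). Of 36 proteasome genes 7 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0077; adjusted p = 0.725 with an estimated correlation). The replication licensing factor Cdt1 rose from 5.75 ± 0.28 to 31.7 ± 17.0 FPKM (2.15, adjusted p = 0.00215). Of 48 DNA replication genes 7 rose and 1 fell (7 and 0 adjusted over the list alone, camera adjusted p = 0.0213; adjusted p = 0.725 with an estimated correlation). After rescaling these counts were 14 and 0. Before rescaling the share up (14.6%) was not far above that of all tested genes, 1934 of 17652. Both list calls ended without replicate 1 (adjusted p = 0.0658 and 0.0577) or 2 (0.0719 and 0.0719) of siEchs1 E2C. Pyruvate kinase, Pkm, rose from 12.9 ± 0.833 to 72.2 ± 30.2 FPKM (2.31, adjusted p = 0.00128). Of 21 glycolysis genes 7 rose and 0 fell (8 and 0 adjusted over the list alone, camera adjusted p = 0.033; adjusted p = 0.725 with an estimated correlation). The call of that list ended without replicate 2 of siCon E2C (adjusted p = 0.0568) and without replicate 2 (0.058) or 3 (0.281) of siEchs1 E2C. Of 28 crotonyl-CoA and histone crotonylation genes 6 rose (21.4%) and 0 fell, also adjusted over the list alone. The list did not pass camera (median 0.43, adjusted p = 0.0715, or 0.725 with an estimated correlation). mRNA decay genes had the largest share up of the lists not called (22.5%). Fry, which tests for shifts on balance one way, is given for the crotonylation list alone (adjusted p = 0.0235). After rescaling 10 genes of the crotonylation list rose and 0 fell. Of 21 genes fixed in advance 4 rose (Gdf9, Zp3, Mos and Hdac3), 5 fell and 12 did not pass, among them Hdac1, Ep300, Cdyl, Mllt3, Acss2 and Sirt1. Without replicate 3 of siEchs1 E2C Ep300 (-1.11, adjusted p = 0.0148), Mllt3 (-1.49, 0.004) and Eif1ax (1.84, 0.00184) passed, and Eif1ax also after rescaling (1.45, 0.0409). Gdf9 was at 1941 ± 1826 against 194 ± 14.2 FPKM, and its call ended without replicate 2 (adjusted p = 0.0547) or 3 (0.0517) of siCon E2C or replicate 2 of siEchs1 E2C (0.0563) and with the E2C libraries alone (0.105). Hdac3, a deacetylase that also removes crotonyl groups, rose from 0.92 ± 0.461 to 5.88 ± 1.09 FPKM (1.86, adjusted p = 0.00312). Glutaryl-CoA dehydrogenase, Gcdh, which forms crotonyl-CoA, was at 8.34 ± 2.95 against 2.35 ± 0.917 FPKM (1.46, adjusted p = 0.0145). Its call ended without replicate 2 of siCon E2C (adjusted p = 0.0646) or of siEchs1 E2C (0.0637) and with the E2C libraries alone (0.0678).

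Among genes with the largest changes at E2C, the X-linked noncoding RNA Ftx fell from 135, 102 and 92.1 FPKM in siCon to 0.49, 0.65 and 0.03 FPKM in siEchs1 (log2 fold change -6.32, adjusted p = 3.9e-07). The growth factor Fgf4 fell from 7.71 ± 0.0839 to 0.277 ± 0.167 FPKM (SD, n = 3, -2.78, adjusted p = 0.000523). The stress gene Gadd45a fell from 7.12 ± 1.11 to 1.73 ± 0.649 FPKM (-1.59, adjusted p = 0.00702). Dph6, an enzyme of diphthamide synthesis, was at 388, 870 and 396 FPKM in siCon and 12.1, 7.0 and 98.9 FPKM in siEchs1 (-4.55, adjusted p = 0.0263). That call ended without replicate 1 (adjusted p = 0.0597), 2 (0.0903) or 3 (0.0647) of siCon E2C or replicate 1 (0.0699) or 2 (0.107) of siEchs1 E2C, and without the filter on low values (0.0805). Mir703, Mir6409 and the neuronal noncoding RNA Bc1 were listed at 0 in all siCon E2C libraries and at 35.7, 67.3 and 54.0 FPKM, 42, 50.2 and 35.2 FPKM, and 39.6, 76.7 and 12.1 FPKM in siEchs1. The small nucleolar RNA Snora21 was listed at 0 in all siEchs1 E2C libraries and at 36.7, 24.6 and 57.4 FPKM in siCon. Hemoglobin Hba-a2, a blood marker, fell from 34.9 ± 14.9 to 1.33 ± 0.548 FPKM (-3.89, adjusted p = 0.00101). Of 7 blood markers 4 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.00476; adjusted p = 0.664 with an estimated correlation).

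Differential expression analysis of siEchs1 against siCon at E2C called 3578 of 17652 genes, 1934 higher and 1644 lower, of which 3444 changed at least 2-fold. After rescaling without mitochondrial and ribosomal RNA, a scaling added after the data had been seen, 2734 genes were higher and 1237 lower, but after quantile normalization 1695 and 1882. With the E2C libraries alone in the fit 1353 genes were called, 532 higher and 821 lower. Without replicate 1, 2 or 3 of siCon E2C the count was 2295, 1982 or 1889, without replicate 2 of siEchs1 E2C it was 1906, and without replicate 3 of siEchs1 E2C it was 6496 (4052 higher and 2444 lower).

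**Figure D2:**
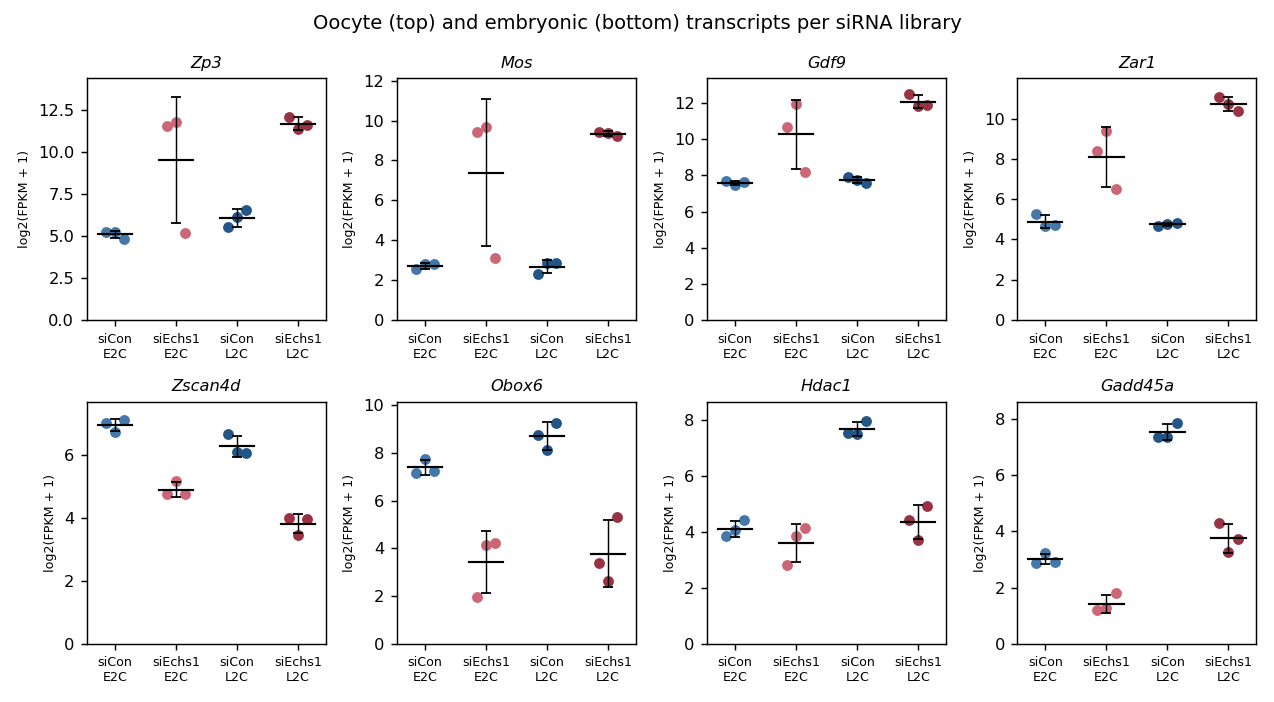
Expression as log2(FPKM + 1) (vertical axes) of 8 genes in the 4 siRNA groups (horizontal axes); dots are libraries, lines group means and bars the SD. Zp3, Mos, Gdf9 and Zar1 are high in siEchs1 L2C and in 2 of 3 siEchs1 E2C libraries, and Zscan4d, Obox6, Hdac1 and Gadd45a are lower in siEchs1 L2C than in siCon L2C.

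The second comparison took the same siRNAs at L2C, where oocyte transcripts were far higher in all 3 siEchs1 libraries than in siCon. Zp3 was at 3410 ± 909 against 69.8 ± 24.5 FPKM (SD, n = 3, log2 fold change 5.62, adjusted p = 0.00312), and Mos at 648 ± 52.0 against 5.51 ± 1.29 FPKM (6.66, adjusted p = 0.000942). The oocyte growth factor Gdf9 was at 4422 ± 1113 against 212 ± 24.2 FPKM (4.36, adjusted p = 0.000317), and its relative Bmp15 at 763 ± 120 against 306 ± 109 FPKM (1.38, adjusted p = 0.00474). Zar1, a maternal-effect gene, was at 1737 ± 433 against 26.0 ± 1.13 FPKM (5.98, adjusted p = 4.9e-05). The gap junction gene Gja4 (960 ± 172 against 13.1 ± 3.44 FPKM, 6.11), the plasminogen activator Plat (755 ± 157 against 11.8 ± 3.44 FPKM, 5.90) and the poly(A)-binding gene Pabpn1l (685 ± 150 against 8.63 ± 1.04 FPKM, 6.13) rose as well, with adjusted p of 0.00011, 6.02e-05 and 0.00137. Of 80 oocyte genes 57 rose and 6 fell (58 and 6 adjusted over the list alone), with a median of 2.92 (camera adjusted p = 1.69e-11; adjusted p = 0.356 with an estimated correlation). Btg4 did not pass (1393 ± 277 against 816 ± 410 FPKM, 0.90, adjusted p = 0.0665). It passed without replicate 3 of siEchs1 E2C (adjusted p = 0.0382) or replicate 1 of siCon L2C (0.0214) and after quantile normalization (0.0324).

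Genes of the 2-cell program were lower in siEchs1 L2C. Zscan4d fell from 78.7 ± 19.99 to 13.3 ± 2.80 FPKM (SD, n = 3, log2 fold change -2.47, adjusted p = 9.86e-05), Zfp352 from 187 ± 34.3 to 11 ± 4.69 FPKM (-4.03, adjusted p = 0.00013), Obox6 from 437 ± 168 to 17.8 ± 18.3 FPKM (-4.92, adjusted p = 0.000201) and Tdpoz4 from 384 ± 90.1 to 23 ± 18.8 FPKM (-4.26, adjusted p = 0.000112). Of 44 genes of the 2-cell transient list 2 rose and 34 fell (2 and 37 adjusted over the list alone), with a median of -2.53 (camera adjusted p = 2.77e-08; adjusted p = 0.356 with an estimated correlation). In the embryonic activation list 3 of 38 genes rose and 19 fell (3 and 20 adjusted over the list alone, median -1.06, camera adjusted p = 0.00794; adjusted p = 0.356 with an estimated correlation). The translation initiation factor Eif1ax rose from 23.3 ± 10.3 to 178 ± 44.7 FPKM (2.94, adjusted p = 0.000683). The heat shock gene Hspa1a fell from 8.71 ± 4.05 to 2.01 ± 1.24 FPKM (-1.68, adjusted p = 0.00355). Ribosome biogenesis genes fell, among them the rRNA methyltransferase Nop2, from 129 ± 41 to 13.9 ± 6.24 FPKM (-3.18, adjusted p = 0.000151), and Polr1b of RNA polymerase I, from 31.2 ± 9.26 to 3.11 ± 0.902 FPKM (-2.95, adjusted p = 7.46e-05). In that list 3 of 72 genes rose and 31 fell, also adjusted over the list alone (median -0.76, camera adjusted p = 0.004; adjusted p = 0.759 with an estimated correlation).

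Lineage and p53 genes were lower as well. Klf5 fell from 43.0 ± 4.99 to 3.06 ± 1.58 FPKM (SD, n = 3, log2 fold change -3.50, adjusted p = 8.01e-05) and Tead4, a trophectoderm regulator, from 14.8 ± 9.55 to 0.353 ± 0.223 FPKM (-3.39, adjusted p = 6.45e-05). In the lineage and pluripotency list 2 of 31 genes rose and 16 fell, also adjusted over the list alone (median -1.15, camera adjusted p = 0.00726; adjusted p = 0.356 with an estimated correlation). Gadd45a fell from 186 ± 38.8 to 13.1 ± 5.08 FPKM (-3.77, adjusted p = 4.9e-05). Of 25 p53 response genes 1 rose and 14 fell, also adjusted over the list alone (median -1.19, camera adjusted p = 0.0191; adjusted p = 0.356 with an estimated correlation). The interferon-induced gene Ifi35 fell from 50.9 ± 19.7 to 1.61 ± 1.24 FPKM (-4.38, adjusted p = 5.55e-05). Of 17 interferon genes 1 rose and 9 fell, also adjusted over the list alone (camera adjusted p = 0.0372; adjusted p = 0.356 with an estimated correlation). That list call ended without replicate 2 of siCon L2C (adjusted p = 0.0622). The deacetylase Hdac1 fell from 204 ± 38.5 to 20.6 ± 8.79 FPKM (-3.32, adjusted p = 0.000105), the acetyltransferase Ep300, which can also crotonylate histones, from 12.8 ± 2.34 to 2.01 ± 0.618 FPKM (-2.20, adjusted p = 0.000427), and Sirt1 from 26.0 ± 6.30 to 8.17 ± 1.57 FPKM (-1.54, adjusted p = 0.00807). Hdac3 rose from 3.37 ± 0.646 to 20.7 ± 6.98 FPKM (2.28, adjusted p = 0.000243). Acss2, Cdyl and Mllt3 did not pass, though Acss2 did without replicate 2 of siCon L2C (-1.28, adjusted p = 0.0443) or replicate 1 of siEchs1 L2C (-1.33, 0.0334). The crotonyl-CoA and histone crotonylation list had 7 genes up and 7 down of 28, also adjusted over the list alone, and did not pass (median -0.22, adjusted p = 0.978; adjusted p = 0.987 with an estimated correlation).

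Metabolic genes moved in both directions at L2C. The complex I subunit Ndufa8 rose from 1.14 ± 0.809 to 124 ± 28.1 FPKM (SD, n = 3, log2 fold change 5.93, adjusted p = 5.66e-05) and fumarase, Fh1, from 6.46 ± 0.834 to 88.3 ± 5.70 FPKM (3.59, adjusted p = 0.000109). Of 75 nuclear genes of oxidative phosphorylation 41 rose and 2 fell (44 and 2 adjusted over the list alone, median 1.69, camera adjusted p = 6.27e-09; adjusted p = 0.592 with an estimated correlation). Of 27 TCA cycle genes 16 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.00726; adjusted p = 0.531 with an estimated correlation). Of 13 genes of the mitochondrial genome 0 rose and 13 fell, also adjusted over the list alone (median -3.08, camera adjusted p = 2.33e-05; adjusted p = 0.531 with an estimated correlation). Among them mt-Atp6 was at 1929 ± 730 against 20260 ± 1914 FPKM (-3.45, adjusted p = 9.32e-05). In proteasome genes 12 of 36 rose and 3 fell (camera adjusted p = 0.0121; adjusted p = 0.759 with an estimated correlation). In branched-chain amino acid catabolism 11 of 23 rose and 3 fell (camera adjusted p = 0.0222; adjusted p = 0.356 with an estimated correlation). Both had these counts adjusted over the list alone as well. In histone variants 9 of 19 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.0411; adjusted p = 0.478 with an estimated correlation). That call ended without replicate 1 (adjusted p = 0.0522) or 2 (0.0768) of siCon L2C. The oocyte linker histone H1foo rose from 127 ± 38.0 to 3566 ± 430 FPKM (4.84, adjusted p = 0.000185), while H2afz fell from 921 ± 182 to 189 ± 2.70 FPKM (-2.26, adjusted p = 0.000223).

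Among the largest decreases at L2C were the lipid droplet gene Cidea, from 77.8 ± 38.5 to 0.0967 ± 0.0513 FPKM (SD, n = 3, log2 fold change -6.01, adjusted p = 4.16e-05), and the metallothionein Mt1, from 1645 ± 952 to 46.9 ± 27.5 FPKM (-5.10, adjusted p = 0.000373). Markers of other cells moved too. Hba-a1 fell from 92.9 ± 19.1 to 6.06 ± 5.76 FPKM (-4.16, adjusted p = 0.00122). Of 7 blood markers 0 rose and 4 fell (0 and 5 adjusted over the list alone, camera adjusted p = 0.0436; adjusted p = 0.531 with an estimated correlation). That call ended without replicate 1 (adjusted p = 0.0705) or 2 (0.0768) of siCon L2C, replicate 3 of siEchs1 E2C (0.053) or replicate 2 of siEchs1 L2C (0.0632). The epithelial marker Epcam fell from 146 ± 46.8 to 10.8 ± 9.16 FPKM (-4.02, adjusted p = 0.000578). Of 6 oviduct markers 0 rose and 4 fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.141). Of 8 cumulus and granulosa markers 3 rose and 4 fell, and of 9 sperm and testis markers 0 rose and 3 fell. Lists not called by camera held, as genes up and down, 4 and 7 of 77 ribosomal proteins (0 and 4 adjusted over the list alone, 6 and 13 after quantile normalization), 9 and 8 of 40 mRNA decay genes, 7 and 9 of 31 fatty acid oxidation genes, 3 and 9 of 21 glycolysis genes (4 and 9 adjusted over the list alone) and 4 and 11 of 28 cholesterol and lipid synthesis genes. They also held 5 and 19 of 52 chromatin modifiers, 5 and 21 of 65 genes of the transcription machinery (5 and 20 adjusted over the list alone), 11 and 11 of 57 splicing genes, 8 and 8 of 46 G2/M genes, 11 and 6 of 48 DNA replication genes (10 and 6 adjusted over the list alone) and 7 and 9 of 28 ATF4 stress genes. At L2C 8611 of 17652 genes were called, 3866 higher and 4745 lower in siEchs1, or 4375 and 4241 after quantile normalization, and 8015 changed at least 2-fold.

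**Figure D3:**
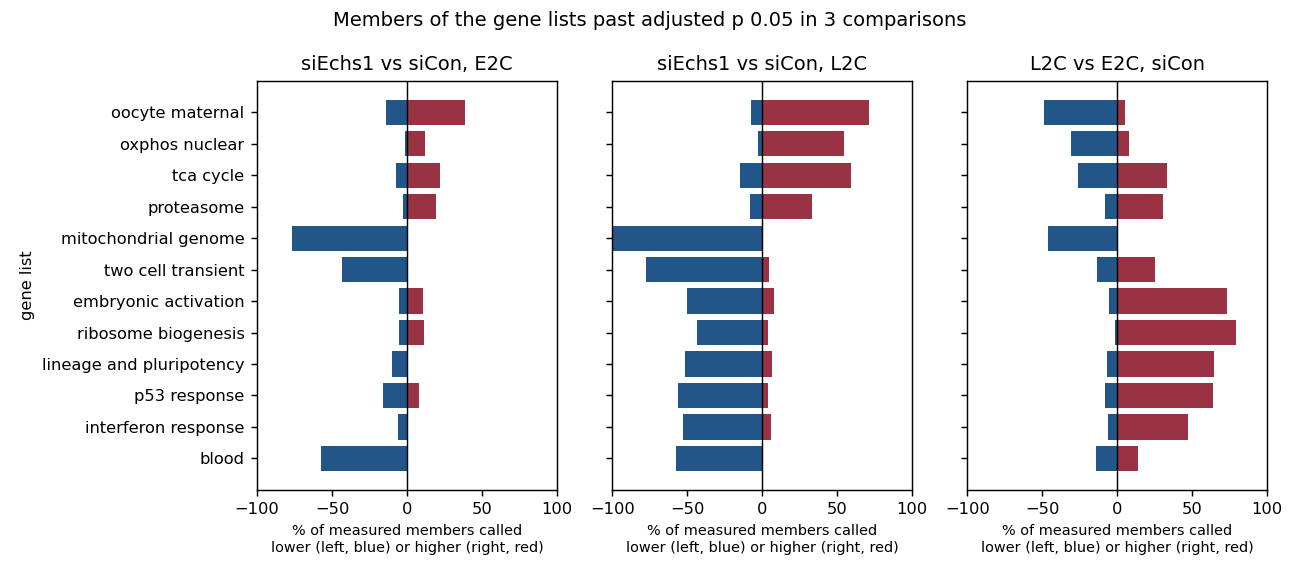
Share of measured list members (horizontal axis, percent) called lower (left, blue) or higher (right, red) in siEchs1 against siCon at E2C and L2C and in L2C against E2C of siCon embryos, for 12 gene lists (vertical axis). At L2C the oocyte list has 57 of 80 genes higher in siEchs1 and the 2-cell transient list 34 of 44 lower.

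The next test set the siRNA effect at L2C against that at E2C. The difference passed for Zar1 (3.21 at E2C and 5.98 at L2C, log2), Cidea (-0.41 and -6.01), Hdac1 (-0.52 and -3.32), Sirt1 (0.56 and -1.54) and Btg4 (-1.0 and 0.90), with adjusted p of 0.0313, 0.000385, 0.00963, 0.0277 and 0.0305. Leaving out 1 library ended the call of Zar1 for 8 of the 12 libraries (adjusted p from 0.0577 to 0.0734), of Sirt1 for 6 (0.0563 to 0.0716) and of Btg4 for 6 (0.0516 to 0.0852). Of 80 oocyte genes 20 had a more positive effect at L2C and 1 a more negative one (24 and 1 adjusted over the list alone, median difference 1.36, camera adjusted p = 9.35e-10; adjusted p = 0.493 with an estimated correlation). Of 72 ribosome biogenesis genes 21 had a more negative effect at L2C and 0 a more positive one (25 and 0 adjusted over the list alone, median difference -1.17, camera adjusted p = 1.57e-05; adjusted p = 0.540 with an estimated correlation). In all, 3039 genes passed, 997 more positive and 2042 more negative at L2C, or 1600 and 1558 after quantile normalization. The count was 1869 without the filter on low values, 1794 with a pseudocount of 0.1 and 1779 with the replicate block. Without replicate 2 or 3 of siCon E2C the count was 1794 or 1566, and without replicate 2 or 3 of siEchs1 L2C it was 1985 or 1291. Across 17652 genes, which are not independent replicates, the log2 fold changes at E2C and L2C correlated with a Spearman rho of 0.528 and a Pearson r of 0.54. They shared 1129 genes higher at both stages and 945 lower at both, against 424 and 442 for independent lists. In opposite directions 66 and 55 genes were called, against 520 and 360.

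Between E2C and L2C, ribosome biogenesis genes rose in control embryos. Nop2 rose from 2.76 ± 0.638 to 129 ± 41 FPKM (SD, n = 3, log2 fold change 5.08, adjusted p = 5.19e-06) and the nucleolar methyltransferase fibrillarin, Fbl, from 9.77 ± 1.09 to 191 ± 58.8 FPKM (4.11, adjusted p = 3.98e-06). Of 72 ribosome biogenesis genes 57 rose and 1 fell (59 and 1 adjusted over the list alone, camera adjusted p = 1.33e-07; adjusted p = 0.436 with an estimated correlation). The stress-induced gene Ddit4 rose from 0.613 ± 0.271 to 168 ± 55.8 FPKM (6.67, adjusted p = 1.92e-06). Pkm rose from 12.9 ± 0.833 to 257 ± 40.7 FPKM (4.21, adjusted p = 5.11e-06). Of 21 glycolysis genes 15 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.00266; adjusted p = 0.436 with an estimated correlation). Embryonic activation genes had 28 of 38 up and 2 down (29 and 4 adjusted over the list alone, camera adjusted p = 0.000583; adjusted p = 0.339 with an estimated correlation). Lineage genes had 20 of 31 up and 2 down, also adjusted over the list alone (camera adjusted p = 0.00922; adjusted p = 0.339 with an estimated correlation). Klf5 went from 2.76 ± 0.397 to 43.0 ± 4.99 FPKM (3.55, adjusted p = 2.68e-05). ATF4 stress genes (17 of 28 up, 0 down) and p53 genes (16 of 25 up, 2 down) rose, both with these counts also adjusted over the list alone (camera adjusted p = 0.000829 and 0.0156; adjusted p = 0.339 for both with an estimated correlation). Ribosomal protein genes had 26 of 77 up and 2 down (25 and 2 adjusted over the list alone, camera adjusted p = 0.0856), or 41 and 0 rescaled. In the 2-cell transient list 11 of 44 genes rose and 6 fell (11 and 11 after quantile normalization), with a median of 0.69 but a camera direction of lower (adjusted p = 0.714). Tcstv3 of that list fell from 549 ± 93.2 to 139 ± 24.3 FPKM (-1.98, adjusted p = 0.0013), and Tdpoz4 rose from 9.42 ± 1.12 to 384 ± 90.1 FPKM (5.19, adjusted p = 1.52e-05).

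Chromatin genes rose and oocyte genes fell over the same interval. Hdac1 rose from 16.5 ± 3.52 to 204 ± 38.5 FPKM (SD, n = 3, log2 fold change 3.55, adjusted p = 2.85e-05), and the acetyltransferase Kat2a from 2.65 ± 0.554 to 27.6 ± 4.83 FPKM (2.96, adjusted p = 1.15e-05). Of 52 chromatin modifiers 30 rose and 1 fell, and of 28 crotonyl-CoA and histone crotonylation genes 14 rose and 0 fell, both also adjusted over the list alone (camera adjusted p = 0.00932 and 0.0156; adjusted p = 0.600 and 0.367 with an estimated correlation). After quantile normalization 9 crotonylation genes rose and 1 fell. Splicing genes had 32 of 57 up and 7 down (33 and 7 adjusted over the list alone, camera adjusted p = 0.0156; adjusted p = 0.436 with an estimated correlation). That call ended without replicate 3 of siCon L2C (adjusted p = 0.0833). The oocyte homeobox gene Obox5 fell from 5425 ± 321 to 183 ± 40.2 FPKM (-4.91, adjusted p = 7.24e-07) and Btg4 from 5442 ± 835 to 816 ± 410 FPKM (-2.88, adjusted p = 7.8e-05). In the oocyte list 4 of 80 genes rose and 39 fell (5 and 39 adjusted over the list alone, camera adjusted p = 1.65e-10; adjusted p = 0.339 with an estimated correlation), or 8 up and 31 down after rescaling. Nuclear oxidative phosphorylation genes (6 of 75 up, 23 down, or 6 and 22 adjusted over the list alone) and genes of the mitochondrial genome (0 of 13 up, 6 down, or 0 and 4 adjusted over the list alone) were lower (camera adjusted p = 3.33e-05 and 0.000837; adjusted p = 0.693 and 0.614 with an estimated correlation). After quantile normalization 35 of the nuclear and 1 of the mitochondrial genes fell. Sperm and testis markers had 1 of 9 up and 3 down, also adjusted over the list alone (camera adjusted p = 0.0492; adjusted p = 0.339 with an estimated correlation). Their median of -0.64 turned to 0.13 after rescaling without mitochondrial and ribosomal RNA. The call ended without replicate 1 of siCon L2C (adjusted p = 0.0756), replicate 1 (0.0544), 2 (0.0568) or 3 (0.117) of siEchs1 E2C or replicate 1 of siEchs1 L2C (0.052). Echs1 itself did not pass (0.14, adjusted p = 0.841). Control embryos had 8870 of 17652 genes called, 6326 higher and 2544 lower at L2C, but 4192 and 4243 after quantile normalization.

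The stage change gave sets of 1330 rising and 268 falling genes, defined on the mean of both siRNA arms. In siEchs1 E2C 1 of the 268 stage-falling genes was higher than in siCon and 130 were lower (2 and 154 adjusted over the list alone, median log2 fold change -1.31, adjusted p = 0.00604 with an estimated correlation). Of the 1330 stage-rising genes 308 were higher and 34 lower (338 and 41 adjusted over the list alone, median 0.63, adjusted p = 0.171 with an estimated correlation). In siEchs1 L2C 167 stage-rising genes were higher and 534 lower (median -0.70, adjusted p = 0.325 with an estimated correlation). For stage-falling genes these counts were 97 and 37 (median 0.38, adjusted p = 0.325 with an estimated correlation). The sets were chosen on these libraries, by a contrast independent of the siRNA effect in a balanced design.

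In the treatment experiment, crotonate embryos were first compared with DMSO embryos. Tacc3, a spindle protein, fell from 225 ± 17.2 to 20.3 ± 6.51 FPKM (SD, n = 2, log2 fold change -3.44, adjusted p = 0.0375), and the spindle pole protein Aspm fell from 821 ± 104 to 102 ± 36.6 FPKM (-3.04, adjusted p = 0.0188). The translation factor Eif3e fell from 43.1 ± 4.15 to 5.07 ± 2.14 FPKM (-2.91, adjusted p = 0.0224), the proteasome subunit Psma7 from 318 ± 24.8 to 62.3 ± 16.3 FPKM (-2.35, adjusted p = 0.0288) and Uqcrc2 of respiratory complex III from 53.8 ± 2.91 to 9.73 ± 3.08 FPKM (-2.38, adjusted p = 0.0309). In multi-copy families, Oas1h fell from 286 ± 50.4 to 43.3 ± 7.75 FPKM (-2.69, adjusted p = 0.0224) and the F-box gene Fbxw28 from 933 ± 252 to 182 ± 60.7 FPKM (-2.36, adjusted p = 0.0392), though copies within each family share sequence. The calcium-binding gene S100a2 rose from 0.23 ± 0.269 to 14.7 ± 6.66 FPKM (3.62, adjusted p = 0.0383). Each of these 8 calls ended when any 1 of the DMSO and crotonate libraries was left out. Each also ended without the filter on low values (adjusted p = 0.142 for Aspm and 0.245 for Tacc3), and Tacc3 and Fbxw28 did not pass after quantile normalization (adjusted p = 0.0541 for both) or with a pseudocount of 0.1 (0.0529 for both). Without the trend Tacc3 (0.0554), Fbxw28 (0.0655), Psma7 (0.0533) and S100a2 (0.0505) did not pass, nor did S100a2 with a pseudocount of 0.1 (0.0793) and Tacc3 after rescaling (0.0557). Of 18 measured genes fixed in advance, among them the Zscan4 genes, Hdac1, Ep300, Cdyl, Mllt3 and Sirt1, 0 passed. Zscan4d (53.2 ± 2.71 against 23.1 ± 20.6 FPKM, 1.5, adjusted p = 0.323), Zscan4c (28.6 ± 1.61 against 14.3 ± 16.6 FPKM, adjusted p = 0.378) and Hdac1 (38.5 ± 4.09 against 23.5 ± 1.09 FPKM, 0.69, adjusted p = 0.307) were examples.

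Few list members were called one by one with crotonate. Oocyte genes had 0 of 79 up and 3 down (2 and 23 adjusted over the list alone, median -0.69, camera adjusted p = 2.27e-06; adjusted p = 0.456 with an estimated correlation). Proteasome genes had 0 of 35 up and 1 down (0 and 11 adjusted over the list alone, median -0.84, camera adjusted p = 7.63e-06; adjusted p = 0.456 with an estimated correlation). Lower lists with 1 gene down were ribosome biogenesis (0 up and 6 down adjusted over the list alone, camera adjusted p = 4.82e-05; adjusted p = 0.615 with an estimated correlation) and nuclear oxidative phosphorylation (0 and 2 adjusted over the list alone, camera adjusted p = 0.000457; adjusted p = 0.691 with an estimated correlation). Lower lists with no member called were DNA replication (1 up and 8 down adjusted over the list alone, camera adjusted p = 0.000136), G2/M genes (0 and 6, 0.000254), the TCA cycle (0 and 7, 0.000378) and the transcription machinery (0 and 5, 0.00562). With an estimated correlation their adjusted p = 0.456 each. Higher lists with no member called were the 2-cell transient list (1 up and 1 down of 43 adjusted over the list alone, median 0.69, camera adjusted p = 2.27e-06; adjusted p = 0.615 with an estimated correlation), the mitochondrial genome (0 and 0 of 13, median 0.48, camera adjusted p = 0.000457; adjusted p = 0.691 with an estimated correlation) and blood markers (2 and 0 of 5, median 0.90, camera adjusted p = 0.00719; adjusted p = 0.456 with an estimated correlation). The call of the 2-cell list ended without replicate 2 of DMSO (median 0.21, adjusted p = 0.0645). The crotonyl-CoA and histone crotonylation list had 0 of 24 genes called (camera adjusted p = 0.625).

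With crotonate, 73 of 13789 genes were called, 29 higher and 44 lower, or 30 and 30 after quantile normalization, and 42 of the 73 were protein-coding (5 higher and 37 lower). Genes shorter than 200 nt made up 23 of the 73, against 2.13% of all genes tested. Snord100 was listed at 0 in DMSO and acetate and at 834 and 475 FPKM in crotonate, and the mitochondrial tRNA mt-Tl1 at 0 and at 393 and 299 FPKM. The count was 1147 (299 higher and 848 lower, including all 73) with the 4 compared libraries alone in the fit, 9 without the filter on low values, 41 without the trend, 31 with a pseudocount of 0.1 and 149 among protein-coding genes alone. It was 9 or 18 without replicate 1 or 2 of DMSO, 19 or 8 without replicate 1 or 2 of crotonate, and 1143 or 1056 without replicate 1 or 2 of acetate. Higher genes outnumbered lower ones without any 1 DMSO or crotonate library (8 and 1, 12 and 6, 18 and 1, 8 and 0), without the filter (7 and 2) and without the trend (25 and 16).

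Acetate against DMSO called 9 of 13789 genes by limma, 1 higher and 8 lower, with 822 at an unadjusted p under 0.05. None of the 9 was protein-coding, and 7 were shorter than 200 nt. The small Cajal body RNA Scarna3a was listed at 0 in DMSO and crotonate and at 15.6 and 16.2 FPKM in acetate (adjusted p = 0.00715). Snord83b, a small nucleolar RNA, was listed at 0 in acetate and at 79.9 and 61.7 FPKM in DMSO (adjusted p = 0.0444). Leaving out replicate 1 of DMSO or either crotonate library ended the call of Scarna3a, and leaving out any DMSO or acetate library that of Snord83b. Neither passed without the filter on low values (adjusted p = 0.0641 and 0.393) or with the 4 compared libraries alone (0.0861 and 0.0508), nor did Scarna3a with a pseudocount of 0.1 (0.146) and Snord83b without the trend (0.0558) or after quantile normalization (0.0864). No member of any list was called, over all genes or adjusted over the list alone. By camera, ribosomal proteins (77 genes, median log2 fold change 0.50, adjusted p = 1.1e-16), nuclear oxidative phosphorylation (74 genes, 0.48, adjusted p = 7.95e-10), the mitochondrial genome (13 genes, 0.47, adjusted p = 0.0136) and the 2-cell transient list (43 genes, 0.14, adjusted p = 0.0296) were higher. The crotonyl-CoA and histone crotonylation list (24 genes, -0.37, adjusted p = 0.0148) and chromatin modifiers (49 genes, -0.43, adjusted p = 0.0136) were lower. For all 6 lists adjusted p = 0.940 with an estimated correlation. Calls of the last 4 ended without replicate 1 of acetate (adjusted p = 0.617, 0.75, 0.507 and 0.75 in that order) or replicate 2 of DMSO (0.236, 0.13, 0.115 and 0.13). Without that acetate library the median of chromatin modifiers turned to 0.19 and that of the mitochondrial genome to -0.01, and without that DMSO library that of the 2-cell list to -0.25. The call of the 2-cell list also ended without replicate 1 (0.0535) or 2 (0.0532) of crotonate. The gene count was 17 without replicate 2 of DMSO, 904 without replicate 2 of acetate, 1 without either crotonate library, 5 after quantile normalization and 0 without the filter on low values or with the 4 compared libraries alone.

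**Figure D4:**
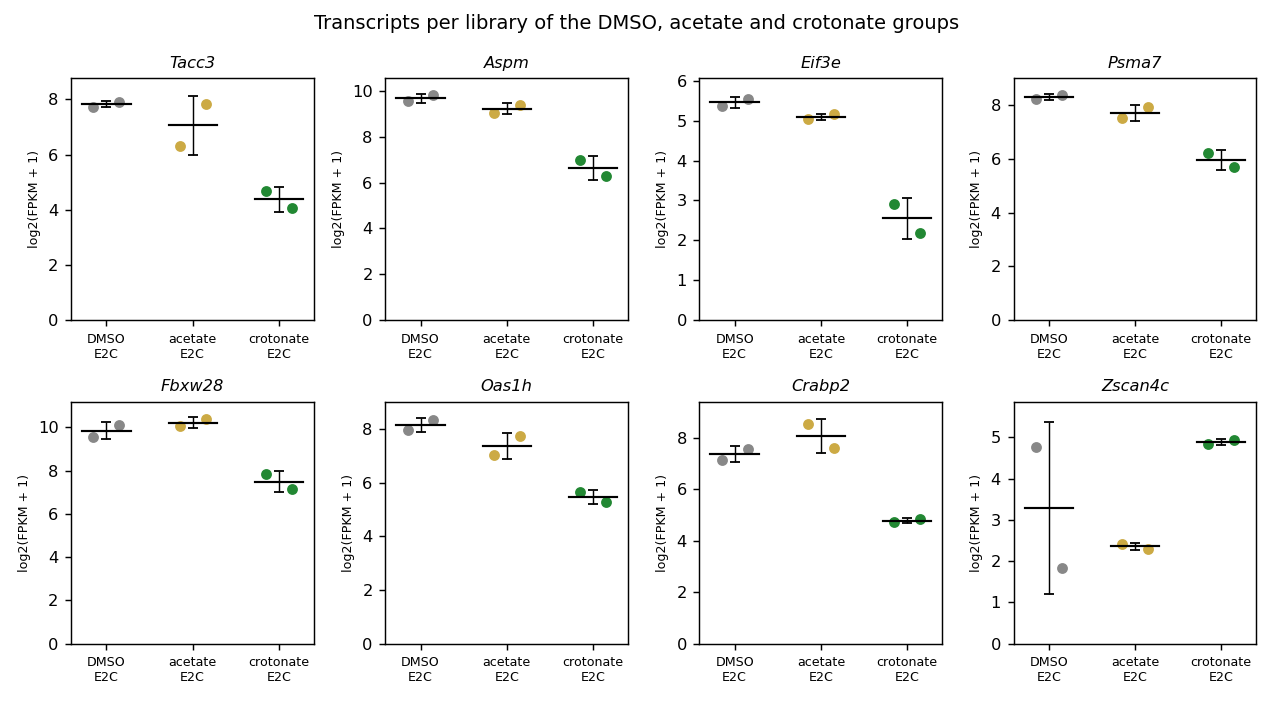
Expression as log2(FPKM + 1) (vertical axes) of 8 genes in DMSO, acetate and crotonate embryos (horizontal axes); dots are the 2 libraries of a group, lines means and bars the SD. Tacc3, Aspm, Eif3e and Psma7 are lowest in crotonate, and the Zscan4c libraries of DMSO lie far apart.

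Crotonate and acetate, carboxylates that differ in chain length and in the double bond of crotonate, were then compared with each other. Since the labels gave no doses, whether the doses matched was not known. The retinoic acid binding protein Crabp2 was lower with crotonate (26.5 ± 1.85 against 279 ± 126 FPKM, SD, n = 2, log2 fold change -3.28, adjusted p = 0.0228), as were Fbxw28 (182 ± 60.7 against 1196 ± 198 FPKM, -2.74, adjusted p = 0.0249), Tacc3 (20.3 ± 6.51 against 151 ± 104 FPKM, -2.68, adjusted p = 0.0444), Uqcrc2 (9.73 ± 3.08 against 52.4 ± 0.212 FPKM, -2.35, adjusted p = 0.0296) and the complex I gene Ndufa1 (36.0 ± 8.50 against 178 ± 7.91 FPKM, -2.30, adjusted p = 0.038). The transcription factor Gtf2b was at 125 ± 9.88 against 482 ± 74.9 FPKM (-1.93, adjusted p = 0.0308). The polymerase subunit Pola1 was higher with crotonate (223 ± 4.71 against 77.2 ± 11.5 FPKM, 1.53, adjusted p = 0.0413). None of these 7 passed when either crotonate library was left out, nor did Tacc3, Uqcrc2, Gtf2b and Pola1 when either DMSO library was left out. Adjusted p then lay between 0.176 and 0.205 for Crabp2, 0.109 and 0.295 for Fbxw28, 0.0828 and 0.413 for Tacc3, 0.0594 and 0.303 for Uqcrc2, 0.198 and 0.386 for Ndufa1, 0.0689 and 0.361 for Gtf2b and 0.102 and 0.386 for Pola1. None of the 7 passed without the filter on low values (0.154 to 0.21). With the 4 compared libraries alone Tacc3, Uqcrc2, Gtf2b and Pola1 did not pass (0.0611 to 0.0998), without the trend Tacc3, Ndufa1 and Pola1 did not (0.0509 to 0.0704), and Tacc3 did not with a pseudocount of 0.1 (0.0538) or under either scaling (0.0562 and 0.0714). For Hdac1 the difference was 1.22 (95% interval 0.53 to 1.91, adjusted p = 0.0789). It passed without replicate 1 (adjusted p = 0.0385) or 2 (0.0421) of acetate. For Zscan4c it was 2.53 (0.65 to 4.41, adjusted p = 0.142). It passed without replicate 1 (adjusted p = 0.0458) or 2 (0.0417) of DMSO and with the 4 compared libraries alone (0.0426). For Zscan4d it was 0.68 (-0.87 to 2.24), for Zfp352 -0.14 (-0.90 to 0.62), for Tcstv3 0.05 (-0.70 to 0.80) and for Echs1 -0.38 (-1.05 to 0.28). The interval lay within a 2-fold difference in either direction for 2023 of 13789 genes.

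By camera, 9 of the 12 lists called were lower with crotonate than with acetate. Nuclear oxidative phosphorylation had 0 of 74 up and 2 down (0 and 23 adjusted over the list alone, median -0.85, camera adjusted p = 1.1e-12), oocyte genes 0 of 79 up and 9 down (0 and 21, -0.57, 3.65e-07) and proteasome genes 0 of 35 up and 3 down (0 and 15, -0.90, 3.65e-07), each with adjusted p = 0.420 with an estimated correlation. After rescaling 5 oocyte and 0 proteasome genes were lower. Ribosomal proteins had 0 of 77 up and 2 down (0 and 7 adjusted over the list alone, camera adjusted p = 4.14e-06; adjusted p = 0.432 with an estimated correlation). That call ended without replicate 1 of acetate (adjusted p = 0.139). G2/M genes had 0 of 46 up and 1 down (0 and 3 adjusted over the list alone, camera adjusted p = 0.000318), the TCA cycle 0 of 26 called (0 and 7, 0.000863), DNA replication 1 of 47 up and 0 down (1 and 8, 0.00171) and the transcription machinery 0 of 64 up and 2 down (0 and 7, 0.0025), each with adjusted p = 0.420 with an estimated correlation. Ribosome biogenesis had 0 of 71 up and 1 down (0 and 0 adjusted over the list alone, camera adjusted p = 0.00544; adjusted p = 0.733 with an estimated correlation). The 2-cell transient list was higher with 0 of 43 up and 1 down (1 and 1 adjusted over the list alone, median 0.39, camera adjusted p = 0.00865; adjusted p = 0.756 with an estimated correlation). Also higher were crotonyl-CoA and histone crotonylation genes (0 of 24 called, also adjusted over the list alone, median 0.30, camera adjusted p = 0.0252; adjusted p = 0.733 with an estimated correlation) and blood markers (0 of 5 called, 3 up adjusted over the list alone, median 1.11, camera adjusted p = 0.0453; adjusted p = 0.420 with an estimated correlation). Without replicate 2 of acetate the calls of DNA replication (adjusted p = 0.0508), ribosome biogenesis (0.121), the TCA cycle (0.0664), the 2-cell list (0.436) and blood (0.255) ended. Without replicate 2 of crotonate those ended of the crotonylation list (0.0582), the 2-cell list (0.115) and blood (0.115). The crotonylation call also ended without replicate 1 of acetate (0.337), and that of blood without replicate 1 (0.0562) or 2 (0.0555) of DMSO.

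Crotonate against acetate called 257 of 13789 genes, 141 higher and 116 lower, or 179 and 97 after quantile normalization and 118 and 48 after rescaling without mitochondrial and ribosomal RNA. Of the 257, 146 were protein-coding and 33 were shorter than 200 nt. Among protein-coding genes alone 94 were higher and 135 lower. The count was 73 (51 and 22) with the 4 compared libraries alone, 9 without the filter on low values, 151 without the trend and 162 with a pseudocount of 0.1. Without replicate 1 or 2 it was 73 or 72 for DMSO, 851 (318 higher and 533 lower) or 1425 (704 and 721) for acetate and 20 or 9 for crotonate. Replicates 1 and 2 of acetate differed in the share of mitochondrial transcripts (20.6% and 11.9%), against 13.4% and 12.2% in DMSO and 19.8% and 16.7% in crotonate.

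The last comparison set the siRNA effect at E2C beside that of crotonate over 13013 genes tested in both experiments, which shared no library. The log2 fold changes correlated inversely, with a Spearman rho of -0.401 and a Pearson r of -0.368 across genes, which are not independent replicates. At a mean of at least 5 FPKM rho was -0.466 over 6877 genes. For siEchs1 at L2C rho was -0.471 with crotonate and -0.0411 with acetate, and for siEchs1 at E2C with acetate it was -0.269. Of the genes called for siEchs1 at E2C and for crotonate, 0 were higher in both, 1 lower in both, 6 higher with siEchs1 and lower with crotonate and 4 the other way, against 1.72, 3.91, 5.44 and 1.24 for independent lists. For siEchs1 at L2C these counts were 0, 1, 24 and 6, against 3.21, 9.15, 10.1 and 2.90. The 1726 genes raised by siEchs1 had a median of -0.52 with crotonate and the 1240 lowered genes one of 0.28. With acetate these medians were -0.30 and 0.29, and for crotonate against acetate -0.24 and 0.01. With an estimated correlation neither set passed in any of the 3 comparisons. Crotonate and acetate effects correlated with r = 0.275, below the 0.497 that 100 simulated draws of unchanged groups gave through the shared DMSO libraries. The covariance was 0.119 against a simulated 0.106, and 60.5% of genes had the same sign, against 66.6%. Of the genes lower with each, 3 were shared, against 0.0255 for independent lists, and part of that excess may come from the shared controls.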

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

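The tests for mixing of embryos, for lag, for a direct effect of Echs1 loss, for the label of replicate 3, for its genes at 0 and for the smallest steps of short genes were chosen only after the result was seen, as were the rescaling without mitochondrial and ribosomal RNA and the left-out libraries for differences between the stages and for lists. Each gene and list here was picked out because its siRNA effect at L2C differed from that at E2C in the test of the difference itself (limma or camera, adjusted p under 0.05). Among genes with large effects at E2C, the difference (L2C minus E2C, log2) was 4.76 for Ftx (SE 0.486, adjusted p = 0.000333) and 5.98 for Dph6 (SE 1.82, 0.0404). Among genes with large effects at L2C it was 2.77 for Zar1 (SE 0.788, 0.0313), 3.46 for Ndufa8 (SE 0.869, 0.02), -5.61 for Cidea (SE 0.587, 0.000385) and -3.62 for Exoc3l2 (SE 1.14, 0.0457). Among genes fixed in advance it was 1.91 for Btg4 (SE 0.539, 0.0305), -2.80 for Hdac1 (SE 0.576, 0.00963) and -2.10 for Sirt1 (SE 0.579, 0.0277). Passed as well, but listed at 0 in every library of a group and so given no difference, were Mir6409 and Bc1 (siCon E2C, adjusted p = 0.0197 and 0.0107), Snora21 (siEchs1 E2C, 0.00568), Snora75 (siCon L2C, 0.00641) and Snord55 (both E2C groups, 0.00658). At L2C, Mir6409 was at 0.90, 7.36 and 6.54 FPKM in siCon and 23.6, 8.75 and 40.3 FPKM in siEchs1, Bc1 at 5.67, 1.32 and 5.60 and at 3.63, 6.88 and 14.6 FPKM, Snora21 at 9.76, 15.2 and 9.43 and at 1.84, 0.88 and 3.51 FPKM, and Snord55 at 77.8, 151 and 106 and at 0, 10.7 and 0 FPKM. Snora75 was at 60.8, 14 and 107 FPKM in siCon E2C, at 0, 0 and 2.69 FPKM in siEchs1 E2C and at 0, 0.12 and 0 FPKM in siEchs1 L2C. Besides Zar1, Btg4 and Sirt1, as given above, leaving out 1 library ended the call of Dph6 for 9 of 12 libraries (adjusted p from 0.0548 to 0.0907) and of Exoc3l2 for 10 (0.052 to 0.103).

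For lists, picked out by camera, the median difference was 1.36 for oocyte genes and 0.933 for nuclear oxidative phosphorylation. It was -1.15 for embryonic activation, -1.17 for ribosome biogenesis, -1.52 for glycolysis, -0.90 for chromatin modifiers, -1.02 for the p53 response and -1.41 for lineage and pluripotency. With an estimated correlation the adjusted p of these lists lay between 0.493 and 0.656. The stage-rising set had a median difference of -1.46 and the stage-falling set one of 2.14, and both passed with an estimated correlation (adjusted p = 0.0363 and 0.00317).

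The first pattern weighed is the high level of oocyte transcripts with low embryonic transcripts in siEchs1 L2C. A mixture of siCon L2C embryos with eggs would scale all embryonic transcripts alike if eggs held none. Of 56 coding genes silent at E2C 16.1% departed from the best common ratio of 0.0896 by more than 2.5 SE (3.69% expected). That criterion came after unequal falls had been seen and no egg library was measured, so mixing stays open. An earlier criterion, replaced after its result, found 0 of 39 such genes higher in siEchs1 L2C and excluded nothing. Embryos halted at the state of siCon E2C would keep its oocyte transcripts. Oocyte genes in siEchs1 L2C lay a median of 1.33 above siCon E2C (35 of 80 higher and 19 lower by limma). Camera did not call the list against all other genes (p = 0.659, or 0.897 with an estimated correlation). The effects that make up this difference had been seen when the test was chosen. It therefore does not decide, and that state and an earlier one stay open. The mitochondrial and ribosomal RNA share as source is argued against by a list median of 2.94 rescaled without it, against 2.92. Total RNA per embryo was not measured. Loss of Echs1 itself may be the source and stays open, though replicate 3 of siEchs1 E2C had Zp3 and Mos near the siCon level at 3.82 FPKM of Echs1.

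The second pattern is replicate 3 of siEchs1 E2C, which lacked the high Zp3 and Mos of replicates 1 and 2. A library of a group without Echs1 siRNA under this label is argued against by its Echs1 level of 3.82 FPKM, where the lowest of those libraries had 24.43 FPKM. Across the 17652 tested genes its Spearman rho was 0.776 to 0.815 with the treatment libraries, 0.74 to 0.783 with its own group and 0.772 to 0.781 with siCon E2C, and its ribosomal RNA CT010467.1 was at 17675 FPKM, against 611 to 3857 FPKM in the other siRNA libraries. For a shallower library the planned limits argued against it, with an estimated depth of 18.29 M fragments and 13667 genes at 1 FPKM, inside the 16.34 to 23.15 M and 13378 to 16703 of the other siRNA libraries; they were not taken to decide it, because the depth rested on the fewest values (1461) and genes at 0, weighed after that result, were the most (35071, against 26670 to 32835), so it stays open. A difference between the embryos of these tubes might be the source as well, and no label records one.

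The third pattern is the share of genes under 200 nt among treatment calls, 23 of 73 with crotonate and 7 of 9 with acetate. Genes were not all independent, as Snord50b and Gm26135 held the same values. Values resting on a few fragments could give such calls and stay open. Over 41 short calls, crotonate against acetate included, the planned estimate by gene length had a median of 36.7 fragments, above the limit of 10. It put the 5th percentile at 16 fragments for genes of 50 to 100 nt and at 0.973 for 1500 to 2500 nt. It was thus taken as too high for short genes, and a count of smallest steps, chosen after that result, gave 7.21. Fragments of a longer gene stay open. Of 23 calls inside one, 10 (43.5%) shared its direction, but many longer genes changed too little to decide. An effect of either treatment on small RNAs was not tested and stays open.

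Other splits of the same libraries bear on the counts of calls. For siEchs1 at E2C, siEchs1 at L2C and the stage change in siCon, 3 libraries against 3 allow 10 splits, too few for a share under 0.05. The real split gave 3578, 8611 and 8870 calls, and the highest of the other splits gave 2, 3 and 2, and 1 split of 10 reached the real count in each case. For the difference of siRNA effects, 4 of 100 splits, the real one included, gave as many genes as the real one (3039). The others gave 3112, 3184 and 8864; the last swaps the siRNA arms at 1 stage and so measures the siRNA effect over both stages, a structure of the samples. That share is under the planned limit of 0.05, but the splits also break the siRNA effects that are compared, so they leave open whether chance gives the difference. For the mean stage change 1 of 100 splits did, with 8743 genes, and the highest other gave 7074. Chance is excluded for the mean stage change, at a share under 0.05.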

How the results depend on the processing

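Protein-coding genes alone, the rescaled values and the block with header numbers were tests chosen only after the result was seen; the others were planned. For the counts, correlations and sets that answer a comparison, 183 values at other settings stayed close (counts within 1.5 times, tests on the same side of the threshold), 54 moved further, 7 lost a call and 0 were reversed. For named genes 8989 values kept direction and call, 553 lost the call, 28 gained one and 0 were reversed. Where a count moved, the cause was not tested, except that fewer libraries or genes entered some fits. After quantile normalization 5 genes were called for acetate against DMSO. Without the filter on low values the counts were 1869 for the difference of siRNA effects, 9 for crotonate against DMSO, 0 for acetate against DMSO and 9 for crotonate against acetate. Without the trend they were 41 for crotonate against DMSO and 151 for crotonate against acetate, and with a pseudocount of 0.1 they were 31 and 162, and 1794 for the difference of siRNA effects. With the E2C libraries alone 1353 genes were called for siEchs1 at E2C. With only the 4 libraries compared, the counts were 1147 for crotonate against DMSO, 0 for acetate against DMSO and 73 for crotonate against acetate. Among protein-coding genes only, 149 were called for crotonate against DMSO and 0 for acetate against DMSO, and after rescaling without mitochondrial and ribosomal RNA 166 for crotonate against acetate.

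The replicate numbers were not taken to pair the libraries, since not every pair of same-numbered libraries deviated together. The correlation of their deviations was -0.0576, 0.0571 and -0.0145 at E2C, 0.111, -0.101 and -0.0864 at L2C by the titles and 0.111, 0.0875 and 0.224 by the headers, and in the treatment groups 0.00402, -0.0957 and 0.16. With the replicate block the counts were 1779 for the difference of siRNA effects, 5887 for the stage change in siCon and 3691 for the mean stage change, the last 3967 with the header numbers.

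With an estimated correlation 0 lists were called in each of the 7 comparisons, against 8 (siEchs1 at E2C), 14 (at L2C), 8 (difference), 13 (stage change), 11 (crotonate against DMSO), 6 (acetate against DMSO) and 12 (crotonate against acetate). The stage sets that no longer passed were the rising set in siEchs1 E2C (median 0.6317), siEchs1 L2C (-0.6994), acetate against DMSO (-0.2728) and crotonate against acetate (0.103), and the falling set in siEchs1 L2C (0.3847), acetate against DMSO (0.4591) and crotonate against acetate (-0.4628). At a mean of at least 5 FPKM the rho between siEchs1 and crotonate effects was -0.4659, against -0.401.

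Leaving out 1 library gave 1889 to 6496 calls for siEchs1 at E2C, 6896 to 10308 at L2C, 1291 to 4061 for the difference, 7302 to 10532 for the stage change in siCon, 7691 to 10257 for its mean, 8 to 1143 for crotonate against DMSO, 1 to 904 for acetate against DMSO and 9 to 1425 for crotonate against acetate, where a group left with 1 library was assumed to vary like the others. The log2 fold change of Echs1 lay between -3.44 and -2.43 at E2C and between -3.45 and -2.70 at L2C. Leaving out 1 library ended calls of 39 of 117 called named genes for siEchs1 at E2C, 3 of 128 at L2C, 4 of 120 for the stage change, 15 of 18 for crotonate against DMSO, 2 of 2 for acetate against DMSO and 24 of 27 for crotonate against acetate. Depth was known only by estimate. In simulated treatment data 3% to 5% of genes changed by 1 (log2) were recovered and 63% to 69% of those changed by 2, so 2-fold differences were mostly not detectable.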

Other observations

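The lists without replicate 3 of siEchs1 E2C were tests chosen only after the result was seen. Without replicate 3 of siEchs1 E2C more members of several lists were called at E2C. Ribosomal protein genes then had 44 of 77 up and 3 down (median 1.13, camera adjusted p = 1.22e-05), against 4 up and 3 down with all libraries (adjusted p = 0.661). TCA cycle genes had 18 of 27 up and 2 down (camera adjusted p = 0.00148), against 6 up and 2 down (adjusted p = 0.0575). Proteasome genes had 26 of 36 up and 1 down and DNA replication genes 21 of 48 up and 3 down. Genes of the mitochondrial genome had 0 of 13 up and 12 down. These camera tests used the preset correlation only.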
